A study of Mus musculus with 10 samples.

How the data were processed

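RNA was measured in whole esophagus of wild-type C57BL/6 mice that went through an experimental model of eosinophilic esophagitis with the hapten oxazolone (OXA), or through the vehicle control. RNA was extracted with TRIZOL, and CEL-Seq libraries, which count the 3′ ends of polyadenylated transcripts, were sequenced on a HiSeq 2500, per the labels' protocols. The 10 libraries fell into 5 vehicle libraries (A1 to A5) and 5 OXA libraries (C1 and D1 to D4), each named as in the sample titles. The letters are nested within treatment and their meaning is not given in the sources used here, so no batch term was fitted. The OXA dose, schedule and route and the sex of the mice are not given in the sources used here either.

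The deposited values are a signal per gene and library, namely gene counts divided by a size factor per library and rounded to 2 decimals, as worked out from the values. FastQC 0.11.5, Trim Galore, cutadapt 1.10, TopHat2 2.1.0, Bowtie2 2.2.6, HTSeq 0.11.2, DESeq2 1.18.1 and the genome build GRCm38 are named, with no role or order, per the submitters' processing notes. The annotation release, the strand setting of the counting, the treatment of reads that match several genes, any filter and any use of molecular identifiers are not given in the sources used here. Reads counted without molecular identifiers are not independent molecules, so every floor below covers counting error only.

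The table held 54446 genes, of which 26612 had a read in some library, 13969 were above 0 in all 10 libraries and 27834 were at 0 throughout. Every value was a whole multiple of a step that was constant within its library. Dividing by that step gave whole reads for 100% of values within a tolerance of 0.006 on the deposited scale. Median-of-ratios factors computed from the recovered reads equalled the steps, with a largest relative gap of 2.37e-08. Recovered reads per library ranged from 3675479 (D2) to 12108822 (A4). A count of 0 allows up to 3 reads in a library, which on the normalized scale was 2.82 on average in the vehicle libraries and 3.50 in the OXA libraries. A fold against a group at 0 in all of its libraries is given as a bound against that mean floor.

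Gene symbols, types and coordinates on GRCm38 were taken from the table. Against the GENCODE M21 annotation, 53229 gene identifiers matched with their version and 54409 without it, and 594 of them carried another symbol there. There were 96 symbols used by more than 1 identifier and 27 symbols that a spreadsheet had turned into dates; identifiers were used throughout.

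The comparison was OXA against vehicle over all 10 libraries. Because the values were normalized and not counts, limma with a mean-variance trend (lmFit, eBayes with trend) was run on log2(value + 1), two-sided, for the 14712 genes with a mean of at least 5 over the 10 libraries. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes, and errors of fold changes are standard errors from limma. Group levels are means ± SD of normalized counts with n = 5 per group unless stated.

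A panel of 37 genes of the disease and its pathway, 43 gene lists of pathways and of cell type markers and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members (39 of them) were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in one direction without reference to other genes, were run beside it. The lists of basophil (2 tested members), thyroid (1), airway epithelium (4) and salivary gland (1) markers were too short for the test. Panel genes also had an exact two-sided permutation test over the 252 splits of the libraries, whose smallest possible p is 0.00794. Named genes were the panel, the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 20 and no overlap between the groups (predicted genes and immunoglobulin or T cell receptor variable segments left out), and up to 4 tested members of each list with the smallest p. Of these, 2 list members are not reported here. Any gene outside that rule is said to have been chosen after its values were seen.

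The gene and list tests were tested on simulated data, with counts drawn from the real means and depths of these libraries and 200 genes changed, over 14756 genes for this comparison. The test recovered 8% of genes changed 1.5-fold, 58% of those changed 2-fold, 90% of those changed 4-fold and 98% of those changed 8-fold. Of 133 calls 6 (4.51%) were false. A list made of changed genes was called, and 0 of 20 lists of unchanged genes were. Genes were drawn independently, so this does not test lists whose members vary together. The skeletal muscle list, for one, had an estimated correlation of 0.778 in the data. With only 200 genes changed, against 29.9% of tested genes called in the data, the shares recovered and false may differ there.

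In 35 alternative settings, results were recomputed with other pseudocounts (0.5 and 5), other filters (none, a mean of at least 1, a mean of at least 20), other scalings (TMM, upper quartile, library totals as CPM, quantile), other variance models, the replicate numbers as a block, a skeletal muscle score or a surrogate variable as covariate, stricter thresholds, other list tests, and each library left out in turn. Count tests were also run on the recovered reads. There edgeR's quasi-likelihood test called 2411 genes higher and 1972 lower, and DESeq2 called 2627 higher and 2249 lower, with 6 adjusted p-values missing under DESeq2. The setting without A5, D2 and D4, the 3 shallowest libraries, was chosen after the data were seen. No pair of libraries of the same group matched within sampling noise, and all 10 carried Y-linked transcripts. Pairs of a vehicle and an OXA library were not compared in this way.

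Capn14, a panel gene, had no entry under that symbol in the table and was not analysed here. Transcripts of closely related genes (Krt6a and Krt6b, the Sprr2, Lce1 and Lce3 clusters, Chil3 and Chil4, the globins, Ear and Rnase2 genes, Slurp1 and Slurp2, H2 genes and Ces1 genes) can share reads, and their split is uncertain. Because the strand setting is not given, values of antisense genes are uncertain too. Software was R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.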

Results

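Polyadenylated RNA of whole esophagus was counted in 10 libraries from wild-type C57BL/6 mice, 5 given vehicle (A1 to A5) and 5 given the hapten oxazolone (OXA; C1 and D1 to D4) to induce experimental eosinophilic esophagitis, an allergic inflammation of the esophagus in which eosinophils enter the epithelium. The series title names IL-13 signalling through the type II IL-4 receptor on epithelial cells, the receptor made of the Il4ra and Il13ra1 chains. The labels speak of mice but say nothing more on how the replicates were obtained, so p-values measure the spread between these samples. Depth ranged from 5094159 (A5) to 12108822 (A4) reads in the vehicle libraries and from 3675479 (D2) to 8364227 (D1) in the OXA libraries. Between 17171 (A5) and 20779 (A4) genes had a read. Krt4 and Krt13, the main keratins of the differentiated esophageal epithelium, took 10.4% ± 1.73 (SD, n = 5) of all reads in vehicle and 5.16% ± 1.60 in OXA. Mitochondrial transcripts took 9.21% ± 2.92 and 7.99% ± 2.83.

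The comparison asked which transcripts of the esophagus differed between OXA and vehicle mice. After OXA, the tissue held far more transcript of the injury keratins Krt6a, Krt6b and Krt16, of the small proline-rich Sprr2 proteins, of the lectin Chil4, of mitotic genes and of leukocyte, chemokine and interferon-inducible genes. It held much less transcript of the late cornified envelope genes of the Lce1 cluster, of filaggrin (Flg) and loricrin (Lor), which build the cornified envelope, and of detoxifying enzymes such as Aldh3a1 and Cyp2f2. Krt6a rose from 202 ± 156 to 63954 ± 14054 normalized counts and Chil4 from 141 ± 135 to 133284 ± 72956, whereas Aldh3a1 fell from 21622 ± 6393 to 126 ± 75.7 and Flg from 61.0 ± 29.2 to 1.57 ± 1.56 (n = 5 per group).

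Of 14712 genes tested with limma, 2309 were higher and 2085 lower in OXA, and 10318 did not pass. Among called genes, 1668 of the higher and 1435 of the lower had no overlap between the groups; 3295 tested genes in all had none, and chance gives 0.794% of genes. On the first principal component, with 49.6% of the variance, vehicle libraries lay between -79.3 and -48.4 and OXA libraries between 51.1 and 83.4. The second, with 14.9%, set A3, A5, D2 and D4 (-54.7 to -19.4) apart from the other 6 libraries, and without the 3 shallowest of these (A5, D2 and D4) 2115 genes were higher and 2016 lower. Spearman correlations over genes were 0.961 to 0.982 for vehicle pairs, 0.928 to 0.968 for OXA pairs and 0.860 to 0.923 between groups. Higher genes made up 52.5% of calls with the deposited scaling and 65.3% after scaling to library totals (CPM), which shifted the median change of all genes from -0.01 to 0.11 on the log2 scale.

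The chains of the type II receptor rose, as did other receptor genes. Whole tissue does not show which cells held these transcripts. Il4ra (ENSMUSG00000030748.9, chromosome 7, 125552120 to 125579774) went from 57.5 ± 10.2 to 189 ± 46.2 normalized counts, a log2 fold change of 1.69 ± 0.20 (adjusted p = 3.71e-05). Il13ra1 (ENSMUSG00000017057.9, chromosome X, 36112110 to 36171559) went from 96.3 ± 27.8 to 251 ± 72.9, or 1.38 ± 0.25 (adjusted p = 9.03e-04). Il2rg, the common gamma chain that pairs with Il4ra in the type I receptor, rose by 1.89 ± 0.30 (adjusted p = 3.79e-04), and the IL-33 receptor Il1rl1 by 1.44 ± 0.24 (adjusted p = 6.04e-04). Il33, an epithelial and stromal alarm cytokine, went from 556 ± 95.5 to 818 ± 208 (0.53 ± 0.18, adjusted p = 0.0420). This call was lost in 12 of 29 alternatives, among them those without A1, A2, A4, A5, C1, D2 or D4 (adjusted p = 0.0518 to 0.0979) and without A5, D2 and D4 (adjusted p = 0.183). The cytokines themselves lay near or under the floor. Il13 averaged 0 in vehicle and 1.65 ± 1.70 in OXA, Il4 0 and 1.01 ± 0.934, and Il5 2.84 ± 1.27 and 0.858 ± 1.28. No difference in them was detectable at this depth. Tslp stood at 7.27 ± 5.76 and 14.8 ± 10.7 and did not pass (adjusted p = 0.278). Of 23 type 2 cytokine and receptor genes 10 passed the filter and were tested. Among these, 8 rose and none fell (9 and 0 adjusted over the list alone), with a median of 1.41 (camera adjusted p = 2.90e-05, and adjusted p = 0.0473 with an estimated correlation).

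Genes that respond to IL-4 and IL-13 rose as a group, 15 of 22 tested (15 adjusted over the list alone) with none lower and a median of 1.28 (camera adjusted p = 1.67e-06, but adjusted p = 0.169 with an estimated correlation). Chil4 (ENSMUSG00000063779.6, chromosome 3, 106201190 to 106219507), a chitinase-like lectin, rose by 10.20 ± 0.54 (adjusted p = 4.71e-08), the largest increase among genes named by the rule. The lipoxygenase Alox15 went from 6.45 ± 13.6 to 1148 ± 1232 (8.18 ± 0.91, adjusted p = 2.32e-05). A2 held nearly all of the vehicle signal, and without A2 the change was 9.10. Socs1, a feedback inhibitor of cytokine signalling, rose by 2.59 ± 0.18, the monocyte and eosinophil attractant Ccl8 by 3.96 ± 0.54, and the resistin-like Retnla from 2047 ± 628 to 6161 ± 3664 (1.47 ± 0.32, adjusted p = 0.00315). Eotaxin-1 (Ccl11) went from 282 ± 64.3 to 554 ± 297 (0.87 ± 0.27, adjusted p = 0.0255). It lost its call in 6 of 29 alternatives, among them those without A1, A2 or A4 (adjusted p = 0.0535 to 0.0591). Eotaxin-2 (Ccl24; 18.1 ± 10.8 and 11.5 ± 8.93, adjusted p = 0.310) and the matrix protein periostin (Postn; 538 ± 146 and 660 ± 178, adjusted p = 0.329) did not pass.

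Across the whole panel of 37 disease genes, 25 were tested, and 14 rose while 4 fell; 19 passed when adjusted over the panel alone. Besides those above, Krt14 (2.18 ± 0.25), Krt16 (8.95 ± 0.71), Mki67 (3.72 ± 0.21), Top2a (3.23 ± 0.18) and the alarmins S100a8 (5.09 ± 0.43) and S100a9 (2.82 ± 0.32) rose. Under the filter, Il13ra2, the decoy IL-13 receptor, averaged 0.826 ± 1.2 and 3.33 ± 2.73, Cdh26 0.688 ± 1.27 and 0.142 ± 0.318, and Ivl 3.88 ± 3.80 and 1.79 ± 2.22. The eosinophil genes Siglecf (0.208 ± 0.465 and 2.36 ± 3.37), Prg2 (0.208 ± 0.465 and 2.45 ± 3.52) and Epx (0 and 0.306 ± 0.684) also stayed under it. The eotaxin receptor Ccr3 was at 0 in all vehicle libraries and above 0 in all 5 OXA libraries, with a mean of 6.47 ± 7.68 (exact permutation p = 0.00794, the smallest the design allows). D2 held 19.91 normalized counts and the other OXA libraries 0.96 to 4.79, so no fold is given. Spink7 was at 0 in all 10 libraries.

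**Figure D1:**
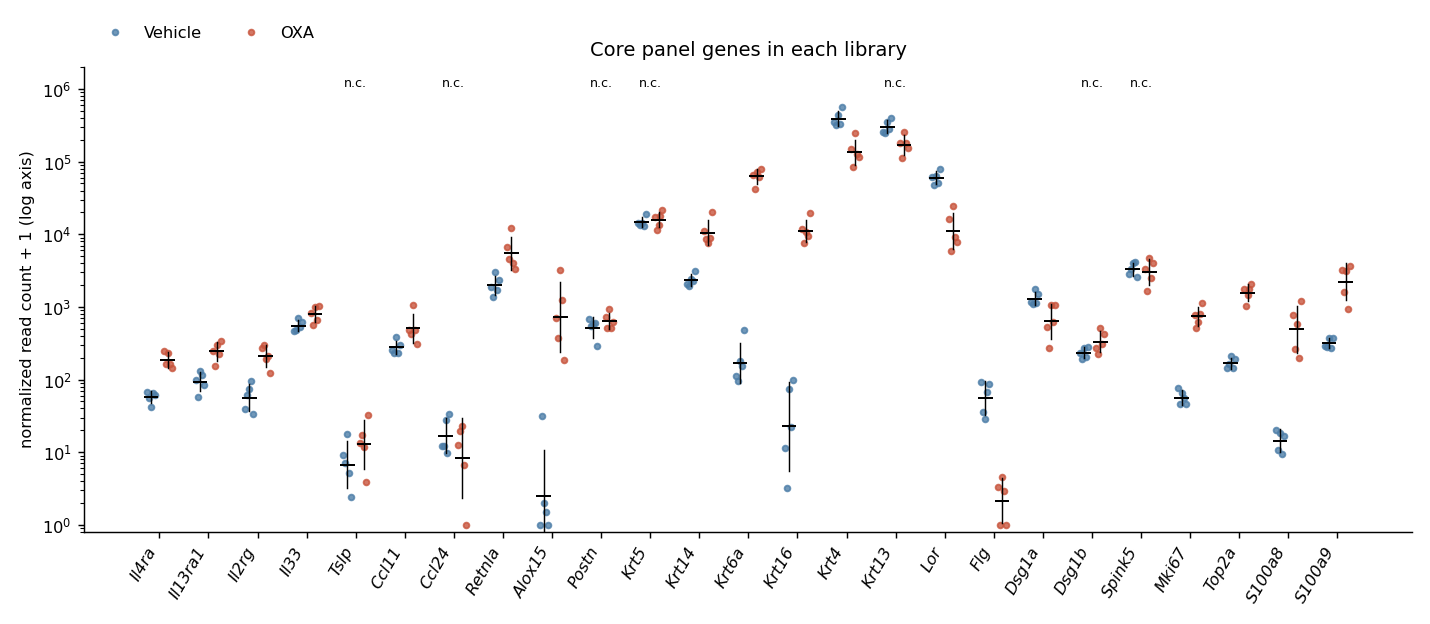
Normalized counts + 1 (log axis) of the 25 tested panel genes in each vehicle (blue) and OXA (red) library, n = 5 per group; horizontal lines are means and vertical bars ± 1 SD of the log values, and n.c. marks genes that did not pass. Krt6a, Krt16 and Alox15 rose by 8.53, 8.95 and 8.18 on the log2 scale, whereas Krt5 (0.12) and Spink5 (-0.12) did not pass.

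Keratins of injured or rapidly growing epithelium rose. Krt6b (ENSMUSG00000023041.7, chromosome 15, 101675723 to 101680287) went from 205 ± 112 to 83025 ± 30440 (8.74 ± 0.36) and its neighbour Krt6a (ENSMUSG00000058354.7, chromosome 15, 101689610 to 101694307) rose by 8.53 ± 0.35, both with an adjusted p of 6.17e-09. Reads can be shared between this pair. Krt17 rose by 6.27 ± 0.38. The epithelial cytokine Il19 was at 0 in all vehicle libraries and at 112 ± 26.2 in OXA, at least 39.5-fold higher. Of 28 tested stress keratin and alarm genes 16 rose and 6 fell (16 and 7 adjusted over the list alone), with a median of 1.58 (camera adjusted p = 6.06e-04; adjusted p = 0.443 with an estimated correlation). Il1a, an alarm cytokine chosen after its values were seen, fell by 2.33 ± 0.71 on the log2 scale (adjusted p = 0.0235). It lost the call without A3 (adjusted p = 0.0650).

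Genes of the cornified envelope moved in both directions, 10 of 46 tested higher and 27 lower (10 and 29 adjusted over the list alone), with a median of -1.25 (camera adjusted p = 4.87e-04; adjusted p = 0.641 with an estimated correlation and 0.171 with fry). Those that rose were led by Sprr2 genes, whose small proline-rich products are crosslinked into the envelope. They included Sprr2f (8.69 ± 0.73), Sprr2e (8.18 ± 0.53), Sprr2d (7.78 ± 0.43), Sprr2h (6.85 ± 0.54) and Sprr2a3 (4.73 ± 0.31). Loricrin fell from 60850 ± 12616 to 12701 ± 7643 (-2.44 ± 0.36), filaggrin by 4.71 ± 0.53, the crosslinking enzyme Tgm3 by 2.28 ± 0.31 and sciellin (Scel) by 1.52 ± 0.21 on the log2 scale. Lce1m and Lce1l fell by 6.38 ± 0.43 and 6.11 ± 0.97. Of these genes, the Sprr2 and Lce1 genes, Lor and Flg lie together on chromosome 3 in the epidermal differentiation complex, where 46 genes between 92014583 and 93449377 were tested and 12 rose, 28 fell and 6 did not pass. All 14 tested Lce1 genes fell (-6.38 to -2.49) and 9 of 10 Sprr2 genes rose, directions kept in each scaling and count test run. Within the Lce3 cluster 5 of 6 fell, and the sixth, at -0.17, had a positive value under edgeR and DESeq2. Genes of the complex chosen after their values were seen included hornerin (Hrnr, -4.30 ± 0.63), repetin (Rptn, -2.16 ± 0.40) and Sprr3, which stood at -0.74 ± 0.30 (adjusted p = 0.0791). Sprr3 passed in 6 of 29 alternatives, among them without D2 (adjusted p = 0.0107).

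**Figure D2:**
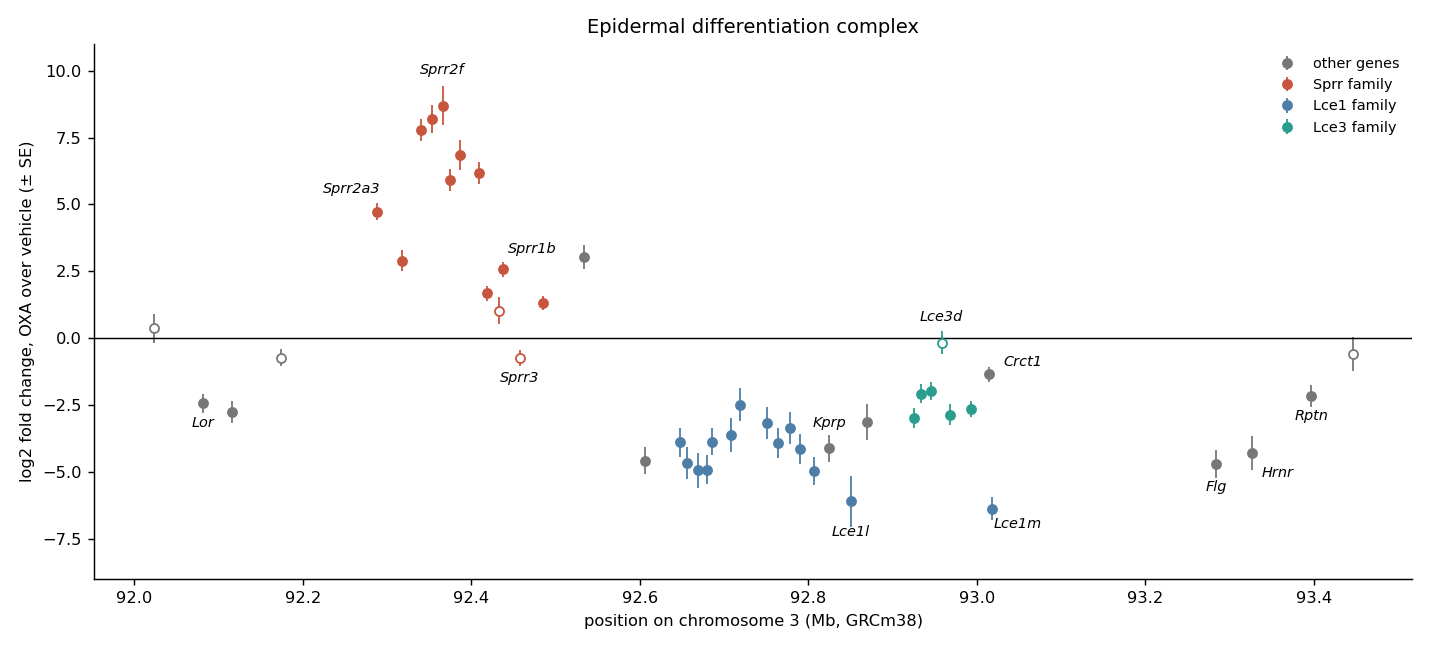
Log2 fold change (OXA over vehicle, n = 5 per group, bars ± SE) of tested genes against their position on chromosome 3 in Mb (GRCm38), coloured by cluster, with filled points for called genes and open points for those not called. Sprr2 genes lie between 1.02 and 8.69, and Lce1 genes between -6.38 and -2.49.

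Keratins of the differentiated layers were lower or did not pass. Krt4 went from 399541 ± 101198 to 143886 ± 60900 (-1.53 ± 0.51, adjusted p = 0.0344) with no overlap between the groups. The call was lost in 12 of 29 alternatives, among them those without A1, A3, A4, A5, C1, D1, D3 or D4 (adjusted p = 0.0504 to 0.0756), without the expression filter (adjusted p = 0.346) and at a mean of at least 1 (adjusted p = 0.111). Krt13, at 306900 ± 65942 and 176009 ± 54453, did not pass (adjusted p = 0.215; exact permutation p = 0.0238), though it passed in 6 of 29 alternatives, and its sign turned under quantile normalization. Krt78 (-2.38 ± 0.34) and Ecm1 (-1.48 ± 0.19) fell, while the protease Tmprss11b (2.0 ± 0.20) and the desmosomal cadherin Dsg3 (1.91 ± 0.22) rose. The suprabasal list, with 5 of 21 higher and 9 lower (median -0.58), was not called (camera adjusted p = 0.125). It passed in 4 of 33 alternatives, among them without D2 (camera adjusted p = 0.0251). In the basal list 5 of 22 rose and 6 fell (median -0.15, camera adjusted p = 0.477). Krt14 rose from 2357 ± 462 to 11260 ± 5139, whereas Krt15 fell by 2.03 ± 0.28, the hemidesmosomal collagen Col17a1 by 1.97 ± 0.22 and Dst by 0.93 ± 0.15 on the log2 scale. Krt5 stood at 14814 ± 2430 and 16346 ± 3990 and did not pass (adjusted p = 0.722).

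Mouse counterparts of genes known to be lower in human eosinophilic esophagitis fell as a group, with 1 of 14 tested higher and 6 lower (1 and 6 adjusted over the list alone), a median of -0.60 and a camera adjusted p of 0.00752 (adjusted p = 0.443 with an estimated correlation). The call was also lost with quantile normalization (camera adjusted p = 0.0646). The desmoglein Dsg1a fell from 1326 ± 280 to 710 ± 348 (-1.04 ± 0.31, adjusted p = 0.0210), a call lost in 4 of 29 alternatives, among them those without A3 or C1 (adjusted p = 0.0563 and 0.0524), and Endou rose by 1.5 ± 0.25. Neither Dsg1b (236 ± 41.9 and 347 ± 119, adjusted p = 0.0919) nor the protease inhibitor Spink5 (3359 ± 675 and 3247 ± 1203, adjusted p = 0.764) passed, though Dsg1b did so in 5 of 29 alternatives, among them without D1 (adjusted p = 0.0263). Counterparts of genes higher in the human disease were not called as a group, 5 of 15 higher and 2 lower (median 0.61, camera adjusted p = 0.0969, but adjusted p = 0.00969 with fry). Alox15, Ccl8 and Samsn1 (2.33 ± 0.42) were higher in it and tissue factor (F3, -1.74 ± 0.20) lower. Lists of epithelial proteases and inhibitors (7 higher and 11 lower of 32, camera adjusted p = 0.387) and of cell junctions (3 higher and 7 lower of 31, camera adjusted p = 0.320) were not called either, though with the muscle score as covariate both passed (camera adjusted p = 0.0439 and 0.0272). Within them the kallikrein Klk6 (5.73 ± 0.48) and Serpina3n (2.92 ± 0.32) rose, and Serpinb13 (-5.03 ± 0.47), Klk5 (-3.02 ± 0.35), the connexin Gja1 (-1.73 ± 0.24) and Cldn23 (-2.54 ± 0.29) fell. The epidermal lipid barrier list was lower, with 13 of 30 lower and 3 higher (13 and 3 adjusted over the list alone; median -0.41, camera adjusted p = 0.00382, adjusted p = 0.631 with an estimated correlation and 0.0582 with fry). It included Ces1d (-2.46 ± 0.18), the fatty acid elongase Elovl6 (-1.71 ± 0.19) and Dgat2 (-1.88 ± 0.22), which makes triglyceride.

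Cell cycle genes rose in 34 of 45 tested and fell in 1 (37 and 1 adjusted over the list alone), with a median of 2.09 and a camera adjusted p of 4.83e-19 (adjusted p = 0.132 with an estimated correlation). The proliferation marker Mki67 went from 56.6 ± 13.3 to 769 ± 234, topoisomerase Top2a from 169 ± 29.2 to 1616 ± 389, the mitotic kinase Plk1 rose by 4.56 ± 0.28 (adjusted p = 1.62e-07) and Ube2c by 2.60 ± 0.19. All 5 OXA libraries lay above all 5 vehicle libraries for each of these 4 genes.

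Immune genes made up most of the other lists that rose. Chemokines rose in 17 of 26 tested with none lower (19 adjusted over the list alone; median 1.21, camera adjusted p = 7.25e-07, adjusted p = 0.132 with an estimated correlation). They were led by Ccl5 (2.99 ± 0.30), Cxcl16 (2.14 ± 0.24), Ccl7 (2.64 ± 0.33) and the interferon-inducible Cxcl9, which went from 24.1 ± 39.3 to 598 ± 237. Interferon response genes rose in 31 of 40 with none lower (34 adjusted over the list alone; median 2.16, camera adjusted p = 1.02e-11, adjusted p = 0.323 with an estimated correlation). Among them were the immunoproteasome subunits Psmb8 (2.99 ± 0.22) and Psmb9 (3.13 ± 0.35), the peptide transporter Tap1 (2.62 ± 0.32) and the GTPase Gbp2 (2.48 ± 0.30). Type 1 and type 17 cytokine genes were not called (2 higher and 2 lower of 6, camera adjusted p = 0.878). Ltb (3.13 ± 0.33) and Stat4 (2.65 ± 0.56) rose, and Il18 (-2.30 ± 0.34) fell. Their median was -0.48, their mean 0.10, and camera and fry gave opposite signs.

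Leukocyte markers rose together. Only members that passed the filter on the mean over all libraries were tested. A marker near 0 in vehicle passes it only where OXA is high, so the shares higher are partly set by the filter. T cell and innate lymphoid markers rose in 19 of 27 (22 adjusted over the list alone; median 1.98, camera adjusted p = 5.47e-09, adjusted p = 0.0425 with an estimated correlation). The costimulator Icos rose by 3.05 ± 0.35, the receptor constant segment Trbc2 by 2.16 ± 0.30, the kinase Lck by 2.50 ± 0.35 and Cxcr6 by 3.4 ± 0.50. B and plasma cell markers rose in 13 of 16 (14 adjusted over the list alone; camera adjusted p = 2.85e-07, adjusted p = 0.0425 with an estimated correlation), with a median of 3.05, or 2.92 with a gene at 0 in vehicle set at its bound. The immunoglobulin constant genes Igha (6.04 ± 0.60), Ighg2b (4.87 ± 0.70) and Igkc (3.75 ± 0.60) and the joining chain Jchain (3.75 ± 0.52) led it. Of 13 NK cell markers 7 were tested, and all 7 rose (7 adjusted over the list alone, median 2.99, camera adjusted p = 1.67e-06, adjusted p = 0.0456 with an estimated correlation). Among them were Gzma (4.87 ± 0.41), Gzmb (4.13 ± 0.55) and Il2rb (3.48 ± 0.54). Dendritic and Langerhans cell markers rose in 18 of 26 (19 adjusted over the list alone; median 1.43, camera adjusted p = 2.43e-09, adjusted p = 0.0456 with an estimated correlation). They included H2-DMb1 (2.70 ± 0.21), H2-Ab1 (2.09 ± 0.25), H2-Aa (2.04 ± 0.25) and Itgax (1.80 ± 0.23).

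Macrophage and monocyte markers rose in 24 of 37 and fell in 2 (25 and 2 adjusted over the list alone; median 1.31, camera adjusted p = 1.96e-07, adjusted p = 0.302 with an estimated correlation). Ccr2 (3.19 ± 0.24), Laptm5 (2.70 ± 0.20) and Ctss (2.31 ± 0.18) rose, while Cbr2, a carbonyl reductase, fell by 2.46 ± 0.23. Of 22 eosinophil markers 10 passed the filter, which Siglecf, Prg2, Epx and Ccr3 did not. Among the 10 tested, 7 rose and none fell (7 adjusted over the list alone, median 1.85, camera adjusted p = 4.66e-04, adjusted p = 0.120 with an estimated correlation). Beside Alox15, these were led by Csf2rb (1.99 ± 0.23), the shared receptor chain for IL-5, IL-3 and GM-CSF, and the ribonucleases Rnase2b (2.45 ± 0.37) and Ear6 (2.28 ± 0.41). Mast cell markers rose in 4 of 11 (5 adjusted over the list alone; median 1.05, camera adjusted p = 0.00362, adjusted p = 0.0929 with an estimated correlation). The mucosal proteases Mcpt1 (5.55 ± 0.61) and Mcpt2 led it, Mcpt2 from 0 in all vehicle libraries to 71.4 ± 34.1, at least 25.3-fold higher. Gzmb, also an NK cell and T cell gene, is a member. The tryptase Tpsb2 rose by 1.05 ± 0.38 (adjusted p = 0.0492), a call lost in 16 of 29 alternatives, among them those without A1, A2, A3, A4, C1, D2 or D4 (adjusted p = 0.0702 to 0.118). Neutrophil markers were not called (6 higher and 2 lower of 11, camera adjusted p = 0.0626). Retnlg (3.70 ± 0.45), Stfa2l1 (3.23 ± 0.60) and Fpr2 (2.62 ± 0.58) rose and the decoy receptor Il1r2 (-3.47 ± 0.26) fell. The list passed in 10 of 32 alternatives, among them those without A1, A2, A3, A4, A5 or D3 (camera adjusted p = 0.00580 to 0.0429). Erythroid genes rose beside the leukocyte lists, 5 of 6 (5 adjusted over the list alone; median 1.38, camera adjusted p = 0.0119, adjusted p = 0.443 with an estimated correlation). Hba-a1 rose by 1.76 ± 0.29 and Hbb-bt by 1.71 ± 0.30. Platelet markers (1 higher of 5, camera adjusted p = 0.262) were not called, and neither of the 2 tested basophil markers passed.

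**Figure D3:**
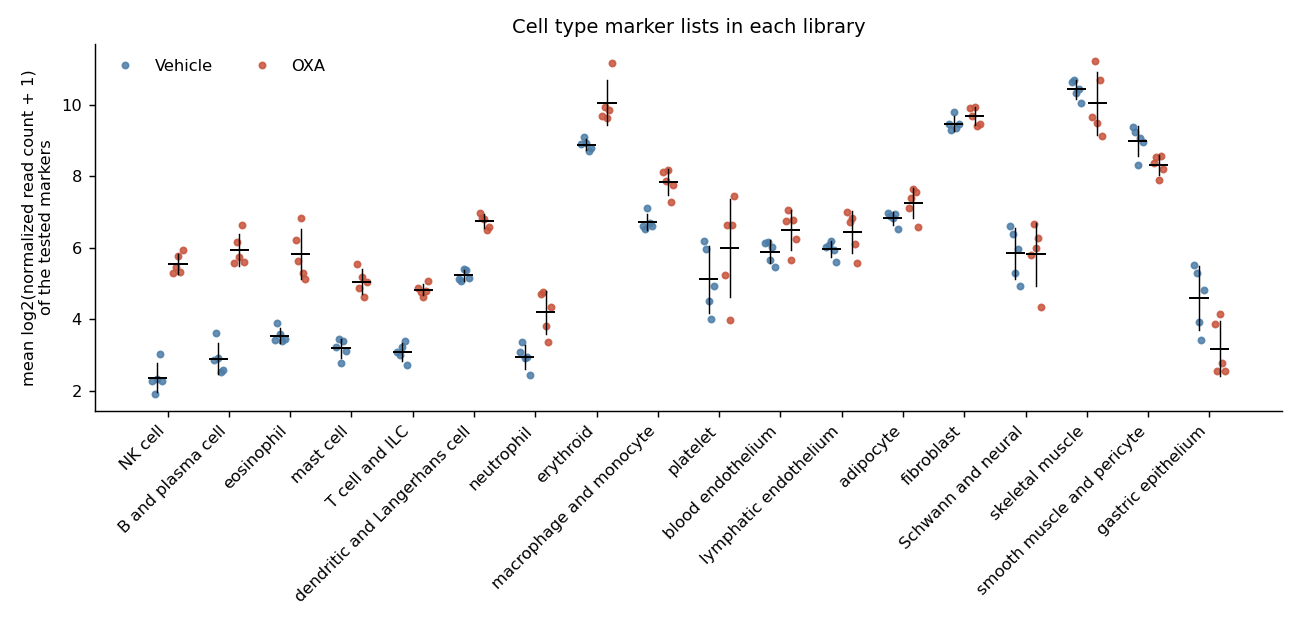
Mean log2(normalized count + 1) of the tested markers of 18 cell type lists in each vehicle and OXA library (n = 5 per group), with lines at group means and bars ± 1 SD. T cell, B cell, NK cell and dendritic cell markers separate the groups, with median changes of 1.98, 3.05, 2.99 and 1.43 on the log2 scale.

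The called stromal and muscle lists had smaller median changes than the called leukocyte lists. Matrix and fibrosis genes rose in 17 of 44 and fell in 3 (19 and 4 adjusted over the list alone; median 0.53, camera adjusted p = 0.00362, adjusted p = 0.515 with an estimated correlation). Fbn1 (1.63 ± 0.22), Vcan (1.78 ± 0.25), Mmp14 (1.35 ± 0.19) and the protease inhibitor Timp1 (3.95 ± 0.57) rose. Fibroblast markers were not called (4 higher and 1 lower of 21, camera adjusted p = 0.320), though Col3a1 (1.2 ± 0.25) and Ly6a (1.56 ± 0.25) rose and Fbln1 (-0.86 ± 0.14) fell. Blood endothelial markers rose in 6 of 20 (7 adjusted over the list alone; median 0.58, camera adjusted p = 0.0104, adjusted p = 0.563 with an estimated correlation). They included the adhesion molecule Vcam1 (1.76 ± 0.18), Ackr1 (1.63 ± 0.30) and Plvap (1.54 ± 0.35). Without D1 the list missed the threshold (camera adjusted p = 0.0512). Smooth muscle and pericyte markers fell in 5 of 17 (5 adjusted over the list alone; median -0.58, camera adjusted p = 0.00879, adjusted p = 0.515 with an estimated correlation). Among these were Tagln (-1.06 ± 0.20), Cnn1 (-1.40 ± 0.27) and Lmod1 (-1.73 ± 0.34). That list missed the threshold without A5, D2 and D4 (camera adjusted p = 0.0775) and with fry (adjusted p = 0.0561). Skeletal muscle markers fell in 7 of 50 and rose in 2 (4 and 2 adjusted over the list alone; median -0.50, camera adjusted p = 0.0200, adjusted p = 0.775 with an estimated correlation). Pvalb (-1.63 ± 0.29) and Fbxo32 (-1.27 ± 0.22) fell and Tnnt1, of slow fibres, rose (2.04 ± 0.48). The call was lost in 10 of 33 alternatives. Besides the estimated correlation, these were the libraries without C1, D2 or D4 (camera adjusted p = 0.0893, 0.102 and 0.222) or without all of A5, D2 and D4 (0.696), quantile normalization (0.0992), edgeR (0.0640), DESeq2 (0.201), the muscle score as covariate (0.359) and fry (0.375). The muscle score is the mean of these same markers, so the loss with that covariate was fixed in advance. Lymphatic (1 higher of 7, camera adjusted p = 0.270), Schwann and neural (1 higher of 16, camera adjusted p = 0.731, median 0.10 but mean -0.02) and adipocyte markers (3 higher and 1 lower of 14, camera adjusted p = 0.117) were not called. Adipocyte markers passed in 3 of 33 alternatives, among them without D4 (camera adjusted p = 0.0181).

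Detoxifying and redox genes fell, 23 of 34 tested with 3 higher (23 and 3 adjusted over the list alone; median -0.93, camera adjusted p = 2.11e-07, adjusted p = 0.155 with an estimated correlation). Aldehyde dehydrogenase Aldh3a1 (ENSMUSG00000019102.10, chromosome 11, 61207537 to 61218721) fell by 7.60 ± 0.36, the cytochrome P450 Cyp2f2 from 17475 ± 4421 to 411 ± 231, the glutathione transferase Gstm2 by 2.52 ± 0.16 and Osgin1 by 2.72 ± 0.22 on the log2 scale. Glucocorticoid-inducible genes fell in 9 of 15 with 1 higher (9 and 1 adjusted over the list alone; median -0.59, camera adjusted p = 0.00530, adjusted p = 0.0901 with an estimated correlation). They included Pdk4 (-2.89 ± 0.36), Ddit4 (-1.5 ± 0.22), Errfi1 (-1.12 ± 0.17) and Angptl4 (-1.76 ± 0.33). Oxidative phosphorylation and fatty acid oxidation genes were not called (1 higher and 8 lower of 48, camera adjusted p = 0.0825). Acadm (-1.0 ± 0.18) and Mdh2 (-0.67 ± 0.14) fell, and the list passed in 5 of 33 alternatives, among them those without A1, A2, A4 or D1 (camera adjusted p = 0.0291 to 0.0462). Mitochondrially encoded transcripts (1 higher of 15, camera adjusted p = 0.365) and immediate early and heat shock genes (4 higher and 8 lower of 26, camera adjusted p = 0.485) were not called. The ribosomal mt-Rnr1 (1.39 ± 0.28) and the transcription factor Junb (1.68 ± 0.19) rose and the chaperone Hspa1a (-1.62 ± 0.18) fell. Markers of neighbouring tissue gave no higher list. Gastric markers had 1 lower of 5, Gkn2 at -2.10 ± 0.54 (camera adjusted p = 0.0772). The list passed in 7 of 29 alternatives, among them those without A4 (camera adjusted p = 0.0236) or D2 (0.0393). Of 4 airway markers 2 fell, among them Cyp2f2, the thyroid list's tested member Foxe1 fell (-2.89 ± 0.31), and the tested salivary marker did not pass.

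**Figure D4:**
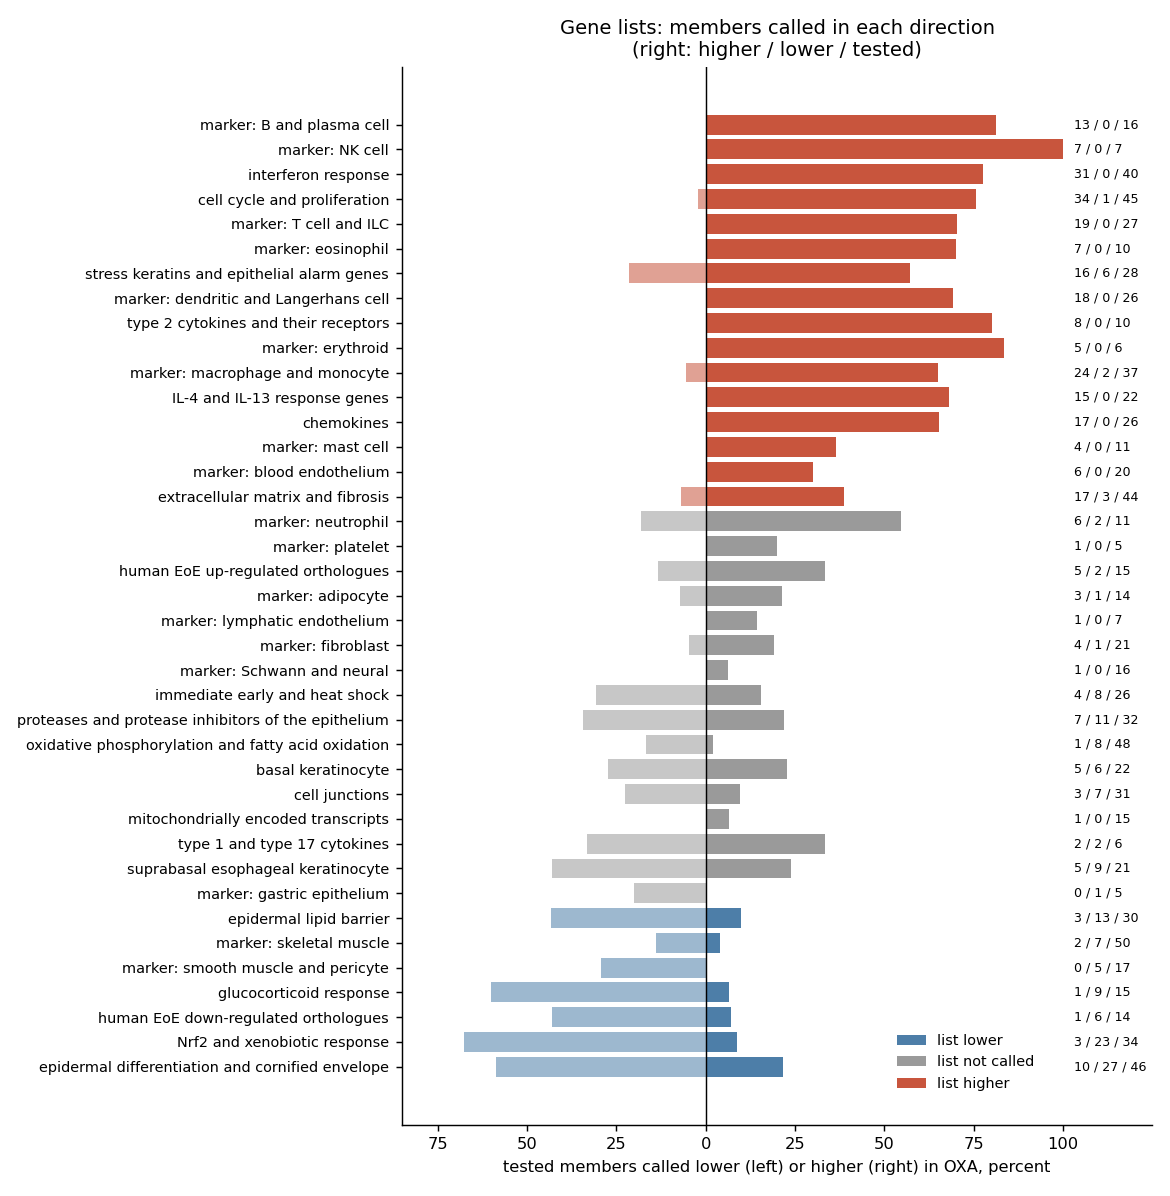
Percent of tested members of each of 39 lists called higher (to the right) or lower (to the left) in OXA against vehicle (n = 5 per group), coloured by whether the list was called higher, lower or neither, with the numbers higher, lower and tested at the right. NK cell markers (7 of 7), B and plasma cell markers (13 of 16) and interferon genes (31 of 40) have large shares higher, and detoxifying genes (23 of 34) and cornified envelope genes (27 of 46) large shares lower.

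Among the 10 largest decreases, Slurp2 (633 ± 269 to 3.24 ± 5.49) and Slurp1 (589 ± 193 to 8.14 ± 5.36), secreted epithelial Ly6-type proteins, fell by 8.01 ± 0.65 and 6.18 ± 0.39 on the log2 scale. Adenosine deaminase (Ada) went from 3732 ± 964 to 43.6 ± 18.7, Dapl1 from 1379 ± 257 to 10.6 ± 6.78, Cyp2a5 from 324 ± 88.8 to 1.28 ± 1.61 and Tmem45a2 from 293 ± 121 to 1.74 ± 2.19. The sulfotransferase Sult1d1 was at 64.2 ± 15.8 in vehicle and at 0 in all OXA libraries, at least 18.3-fold lower. With Aldh3a1, Lce1m and Lce1l these complete the 10, and the 10 largest increases were Chil4, Krt16, Krt6b, Sprr2f, Krt6a, Sprr2e, Alox15, Sprr2d, Sprr2h and Il19.

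In all 16 lists were called higher and 7 lower with the preset correlation, and 5 higher and 0 lower with an estimated one, namely the type 2, T cell, B cell, NK cell and dendritic cell lists. Of 100 groupings of these libraries into 5 and 5, the real one included, 18 reached 16 lists in their larger direction. The 7 lists lower were reached in 78, but there the larger direction of other groupings was set against the smaller real one. Chance was not excluded for the number of lists.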

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

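The tests on transcripts inside genes, both tests on leukocyte markers, the share of replication genes with a higher OXA mean, and the genes Hrnr, Cenpe and Il1a were chosen only after the results were seen. Redrawing the 10 libraries into 5 and 5 tested the counts of the comparison. In 1 of 100 splits, the real split alone, as many genes were higher (2309 against 0 in the highest other split). The same held for genes lower (2085 against 0) and panel genes called (18 against 0). The other splits mix OXA and vehicle libraries, so any difference between the groups adds to their spread and lowers their counts. The real split ranked first of the 100 drawn, but counts of 0 elsewhere were likely in advance. Differences that run with the title letters, nested within treatment, are not tested by this. A split has no direction, so each other split entered with its larger list count, higher or lower. With the real split included, 18 of 100 reached the real 16 lists higher (highest other 19), so chance cannot be excluded there. The real 7 lists lower, its smaller direction, was set against that larger count and was reached in 78 of 100 (highest other 19). These counts are unlike, so the test cannot decide for lists lower, and chance is not excluded.

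In 22 of 402 groups of 5 libraries, 1 library lay apart from the other 4 by more than 0.71 of the group's range, where chance gives about 1 in 20. Among vehicle libraries, A5 held 291.9 normalized counts of Postn (others 546.72 to 677.95), 1639.78 of Col17a1 (others 1160.48 to 1280.18), 19057.8 of Krt5 (others 13142.6 to 14447.1), 153.1 of Osgin1 (others 117.89 to 126.74) and 1.43 of Sprr2e (others 0). A4 held 79.98 of Socs1 (others 43.5 to 51.64), 748.38 of Hrnr (others 1495.42 to 1778.23) and 0.52 of Stfa2l1 (others 0). A2 held 30.75 of Alox15 (others 0 to 0.97) and 5.25 of Sprr2d (others 18.49 to 22.89). Among OXA libraries, D4 held 408.67 of Socs1 (others 288.27 to 308.38), 336.83 of Cxcr6 (others 63.37 to 92.9), 9975.59 of Hba-a1 (others 2869.56 to 3952.07) and 4516.07 of Hbb-bt (others 1155.07 to 1640.55), and its erythroid score was 11.1611 (others 9.62545 to 9.93452). D1 held 23.46 of Mcpt1 (others 105.35 to 130.53), 14.22 of Mcpt2 (others 74.7 to 105.01), 140.74 of Cnn1 (others 188.29 to 211.65) and 147.85 of Cenpe (others 217.4 to 251.65). D2 held 141.22 of Scel (others 63.26 to 78.62) and 72.42 of Ackr1 (others 189.78 to 252.22), and D3 held 0 of Il1a (others 10.66 to 19.91).

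Among genes fixed in advance that missed the expression filter, 2 were at 0 in all vehicle libraries and above 0 in all OXA libraries. They were Ccr3, with an OXA mean of 6.474 normalized counts, and Pou2af1, a coactivator of B cells, with an OXA mean of 8.372 ± 5.61.

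Leukocyte markers were higher in OXA while erythroid genes rose too. If blood of unchanged composition left in the tissue were the whole cause, lymphocyte markers would rise no more than globin genes. The mean of 50 lymphocyte markers rose by 2.36 and that of the globins by 1.56. The difference of 0.81 (spread 0.52, exact permutation p = 0.0476) went against that prediction. Lymphocyte markers near 0 in vehicle passed the filter only where OXA was high, though, which favours such a difference. The composition of blood was not measured either, so the test cannot decide on blood as the source. In D4, however, lymphocyte minus globin score was -7.76, below the vehicle libraries (-7.47 to -7.07), whereas the other OXA libraries lay at -6.35 to -5.98, so a larger share of blood in that library stays open. A smaller share of muscle would raise the markers of all other cell types alike. Lymphocyte markers rose by 2.15 more than fibroblast markers (exact permutation p = 0.00794), whose rise was 0.21. This argues against a smaller share of muscle as the whole cause, though the filter favours this difference too. More leukocytes in the tissue after OXA may account for the rise, a hypothesis that these tests leave open and that counts of cells would have to test.

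Short transcripts annotated inside genes on the same strand were higher in OXA, with 73 of 378 called higher, 0 lower and a median of 0.75 on the log2 scale, against 0.13 for 99 such features outside genes. If a higher level of the host gene were the cause, features in unchanged hosts would lie near 0. The 249 features in hosts that were not called had a median of 0.75 (quartiles 0.29 to 1.28). A host that was not called can still have risen, since the test recovered only 8% of simulated 1.5-fold changes. The 49 features in hosts called lower had a median of 0.34 (quartiles -0.04 to 0.70), so these values cannot decide on the host gene. Genomic DNA in the libraries would raise antisense features too, and 220 of them had a median of -0.30 (quartiles -0.87 to 0.37). Because the strand setting is not given, antisense values are uncertain, and this test cannot decide on genomic DNA. A larger share of intronic reads in OXA libraries could account for the pattern, since features inside genes rose by 0.62 more than those outside, but the score of these features did not separate the groups beyond the spread of the libraries (difference 0.80, exact permutation p = 0.0556). A5 (2.05) and A3 (2.85) had the lowest of these scores, and whether RNA quality, handling or transcription differed between the groups stays open.

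Mitotic genes rose more than replication genes. Of 55 genes of the G2 and M phases, 47 rose and 1 fell (median 2.12), and of 50 S phase genes 18 rose and 3 fell (median 0.62), with a difference of scores of 1.46 (exact permutation p = 0.00794). A low baseline of mitotic genes is argued against by bins matched on vehicle level, where the medians still differed by 1.58 on average (spread 0.54, range 0.83 to 2.01). Replication genes may also be read in cells that do not divide, which would dilute their fold. Of them 86% (43 of 50, exact 95% binomial interval 73.3% to 94.2%) had a higher OXA mean, as that explanation needs. More dividing cells without such dilution would give this too, so the share does not single it out. The interval treats genes as independent, which genes of the same libraries are not. A longer or arrested mitosis after OXA was not tested and stays open.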

How the results depend on the processing

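The setting without A5, D2 and D4 was chosen only after the results were seen. In each of the alternatives, all genes called in the comparison that were in the fit kept their direction. Leaving out each library in turn gave 1896 (without C1) to 2361 (without D2) genes higher, 1686 (without A3) to 2201 (without D2) lower, 15 to 17 lists higher, 6 to 9 lists lower and 15 to 18 panel genes called. Stricter criteria called fewer genes by construction, 1276 higher and 994 lower with a log2 fold change of at least 1, and 1398 and 1137 at an adjusted p under 0.01. Fitting the replicate numbers that A1 to A4 and D1 to D4 share as a block gave 1427 higher and 1084 lower, against 1707 and 1417 for the same 8 libraries without the block. Correlations of same-numbered deviations were 0.19, -0.23, -0.13 and 0.01, not every vehicle library correlated best with its own number, and the pairing was not used. With an estimated correlation 5 lists were higher and 0 lower, and fry called 3 lower; the cause was not tested.

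Of 155 named genes 145 were called, and 138 of these kept their call in all alternatives that tested them. The other 7 were Ccl11, Dsg1a, Il1a, Il33, Krt4, Tpsb2 and Stat4, the last lost with the block alone (adjusted p = 0.05005). Most named genes were chosen for a small p or a large change, so this share does not stand for all calls. Of all called genes in the fit, 3590 of 4387 kept their call without A3. The share was lowest with the block (2478 of 4384) and complete with 1 surrogate variable (4394 of 4394). Of 23 lists called, 5 kept their call in every alternative. Among these named genes and lists, signs turned only in results that were not called. The genes were Krt13 (0.22 with quantile normalization), Postn (-0.064 without A5, D2 and D4) and Spink5 (0.013 with CPM, and from -0.27 to 0.10 with a library left out, the highest without D1). Lists that turned, given by camera adjusted p, were the human counterparts higher in the disease (0.734 with shared members left out), Schwann and neural markers (0.941 on the 8 libraries, 0.795 with the block, 0.222 to 0.945 with a library left out, turning without A5 at 0.896 and without D1 at 0.909) and type 1 and type 17 cytokines (0.0676 without a filter, 0.181 at a mean of at least 1, 0.345 with fry). The cause was not tested. Krt4 and Krt13 are the most abundant keratins here, and their calls differed between alternatives. Without a filter Krt4 kept the fold change of the main fit (-1.53 on the log2 scale) with a larger standard error (0.95). There the error and not the fold changed, and causes in the other alternatives were not tested. Krt13 passed without the trend (adjusted p = 0.0245) and Krt4 had an adjusted p of 0.346 without a filter and 0.00478 with edgeR. Low depth limits the cytokines Il4, Il5 and Il13 and the eosinophil genes Siglecf, Prg2 and Epx, whose group means lay under or near the floor of 3 reads per library.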

Other observations

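The gene families in the next paragraph, and Gsdmc2 and mt-Co1, were chosen only after their values were seen, whereas the tests on neighbouring genes were set before their result was.

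Some gene families, several with members in the fixed lists, changed mostly in one direction. All 9 tested guanylate-binding protein genes rose (median 2.32, with Gbp4 at 4.09 ± 0.77), as did all 12 tested genes of the Ifi200 family of nucleic acid sensors (0.70 to 4.64, with Ifi214 at 4.64 ± 0.56) and 9 of 10 classical and nonclassical class I H2 genes, led by H2-Q7, which went from 159 ± 128 to 2090 ± 321 normalized counts. In the other direction, 6 of 7 mu-class glutathione transferases fell (Gstm3 from 91.9 ± 25.4 to 1.03 ± 0.720), together with 3 of 4 alpha-class ones and 9 of 11 carboxylesterases (Ces1h by 4.49 ± 0.35 on the log2 scale). Members of these families that were called kept their direction under each scaling and count test run. Other families were mixed, such as kallikreins (3 of 11 higher and 3 lower), Serpinb genes (1 of 17 higher and 6 lower) and alcohol and aldehyde dehydrogenases (4 of 23 higher and 11 lower). The families were not tested as groups. The gasdermin Gsdmc2, a pore-forming protein of epithelium, rose from 1.60 ± 0.423 to 55.9 ± 44.3 (adjusted p = 2.23e-05), and of 5 tested gasdermins 3 rose and 1 fell. Members of such families can share reads, so single values within them are uncertain.

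Interferon genes varied among vehicle mice. The mean log2 level of the 40 tested members was 4.44 in A5, 5.03 in A2, 5.37 in A1, 6.43 in A3 and 6.92 in A4, and 7.39 to 8.14 in the OXA libraries. The mitochondrial ribosomal RNA mt-Rnr1 rose from 4562 ± 2038 to 11226 ± 2424 (adjusted p = 0.00207), while mt-Rnr2 (49070 ± 15859 and 77624 ± 16884, adjusted p = 0.141) and the messenger mt-Co1 (47907 ± 16642 and 32359 ± 16957, adjusted p = 0.252) did not pass. In 3 of 29 alternatives mt-Rnr2 passed.

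The opposite blocks on chromosome 3 raised the hypothesis that neighbouring genes change alike across the genome. Over 13352 pairs of adjacent tested genes, Spearman's rho of their log2 fold changes was 0.114, above the highest of 1000 shuffles of gene order (0.0325). Without pairs that share a symbol stem, rho was 0.0772 over 12614 pairs (highest shuffle 0.0312), so such pairs alone do not account for it. Related neighbours with different stems, and other pairs of the chromosome 3 region that raised the hypothesis, stayed in. The test therefore cannot exclude gene families. Each rho is a correlation across genes, which are not independent replicates. Shared regulation, overlapping transcripts or reads running into a neighbour may each add to so small a value.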
